A study of Homo sapiens with 118 samples.

How the data were processed

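Gene expression was measured on 118 microarrays (Affymetrix Human Genome U133 Plus 2.0, a chip of short-oligonucleotide probe sets) from airway epithelial brushings of 86 people. The labels name asthmatics at baseline (42 arrays), healthy people (28), smokers (16), and asthmatics after fluticasone (19) or placebo (13). Per the labels, the starting material was total RNA amplified with the NuGEN Ovation system and labelled by the manufacturer's usual procedure. The authors deposited log2 expression values, 1 per probe set and array, summarised with RMA per the submitters' processing notes. The version of RMA and whether all arrays were summarised together are not given in the sources used here. The deposited log2 values ran from 3.42 to 14.3, array medians ran from 5.92 to 6.11, and no gene had been centred, so the values entered the tests as they were. The raw probe intensities were not analysed here. The number of arrays limits the precision of every value.

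The table held 54675 probe sets, of which 62 were array controls, 41091 carried 1 gene symbol, 1801 several and 11721 none. Entrez identifiers linked 41037 of the single-gene probe sets to a RefSeq gene table, which changed 0 symbols. For privacy, 95 probe sets of sex-linked genes and 4 further probe sets that tracked them were left out, which kept 54514 probe sets. A gene was represented by its probe set with the highest mean, which gave 19739 genes, and 10511 of them had more than 1 probe set. No genome positions were used. Probe sets of close paralogs (TPSAB1 and TPSB2, CST1 and CST4, AKR1C1 and AKR1C2) share sequence, so the values of such pairs are not independent.

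Sample codes placed the arrays in 4 sub-studies. The treatment sub-study held 35 asthmatics and all 32 arrays after treatment. A mixed sub-study held 7 asthmatics and 11 healthy people, a smoking sub-study held 16 smokers and 15 healthy people, and the other 2 healthy people came from another sub-study. No other batch is named in the labels. The codes also paired the 2 arrays of 32 treated asthmatics. After removal of the group means, the 2 arrays of a person correlated with a median of 0.619 (0.193 to 0.852), against -0.0368 for arrays of different people. That correlation was over 0.1 in 32 of 32 people, and 27 of 32 arrays after treatment correlated best with the same person's array before it. The highest correlation of 2 arrays was 0.995, and the lowest median correlation of an array with the others was 0.946. In 4 arrays this median was under 0.96: smoker replicates 1, 15 and 16 and asthma replicate 31.

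Tests used R 4.3.3 with limma 3.58.1, data.table (1.17.8) and statmod 1.5.0, after preparation in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. Figures were drawn with matplotlib 3.10.9. For asthma, smoking and healthy groups, limma (lmFit and eBayes) fitted a mean per group to 86 arrays, 1 per person. For treatment, limma was fitted to each person's change after minus before, so each person was their own block. Tests were two-sided, and genes were called changed at a Benjamini-Hochberg adjusted p under 0.05 over all 19739 genes. Adjusted p-values of genes and of lists come from these limma fits. Permutation tests used 100000 draws unless called exact, so 1e-05 is the smallest p they can give.

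The comparisons, the tests, 25 gene lists and the rule for named genes were fixed before the data were examined. The lists covered a type 2 epithelial response (genes induced by interleukin-13 in airway epithelium), cell types (mast cell, eosinophil, neutrophil, T and NK cell, B and plasma cell, macrophage, dendritic and Langerhans cell, goblet cell and mucus, ciliated, club, basal, squamous epithelium, ionocyte and neuroendocrine, submucosal gland, stroma and endothelium, red blood cell), and responses (AHR targets, NRF2 targets, glucocorticoid targets, NF-kB cytokines, interferon response, cell cycle, unfolded protein response, immediate early genes). Each list was tested with limma's fry, which asks whether its genes move on balance in 1 direction and does not compare them with other genes, and its p was adjusted over the 25 lists. The other list test was limma's camera with an estimated correlation between genes, which compares a list with the remaining genes. Members were also counted as changed when adjusted over the list alone. The median of a list's members, the difference of its mean or fry's direction differed in sign for 5 lists in asthma, 5 in smoking, 4 between asthma and smoking, 3 between the arms, 4 in the fluticasone arm and 5 in the placebo arm, and 0 of these lists was called.

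The named genes were the 10 largest rises and 10 largest falls among genes past the threshold, up to 4 changed members per list with the largest change, and a preset set. Genes whose signal can follow an inherited deletion or allele, such as the HLA genes, were left out of the names. POSTN, CLCA1, mast cell genes and FKBP5 have been reported from these samples, so their lists are not independent evidence of direction.

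Alternatives were quantile normalization between arrays, centring each array on its median, leaving out the dimmest 40% of genes, averaging a gene's probe sets, testing all probe sets, eBayes with trend and robust settings, array quality weights, and a 3 prime minus 5 prime RNA term. Further alternatives were the ciliated list mean as a covariate, only the groups compared, sub-study as a block, subsets of people, treatment without pairing, and person as a random block. The estimated correlation for that random block was 0.484. Alternatives chosen after seeing the data were leaving out the 4 arrays with low agreement, the macrophage list mean as a covariate, and leaving out each array or person in turn. The pipeline was tested on simulated data with independent genes, in which 200 genes were shifted by a log2 of 0.5, 1 or 2. At a log2 shift of 1 it recovered 100% of 67 genes between the groups of 42 and 28, and 85.1% between groups of 7 and 11. At a shift of 0.5 these shares were 89.6% and 47.8%. Between the treatment arms it recovered 97.0% at a shift of 1 and 77.6% at 0.5. Genes of the real arrays are not independent, so these shares need not hold for them. The share of false calls was 2.55% to 7.27%, and the shifted list was called in each comparison with 0 other lists.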

Results

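Brushings of the airway lining came from 42 people with asthma before treatment, 28 healthy people and 16 smokers, 1 array per person. Of the asthmatics, 32 gave another brushing after a course of fluticasone, an inhaled glucocorticoid (19 people), or of placebo (13 people). Signs of RNA integrity, measured as the 3 prime minus 5 prime signal of control transcripts, differed by -0.13 log2 between asthma and health (permutation p = 0.461), by -0.21 between smokers and health (p = 0.284), and by 0.22 between the arms' changes (p = 0.0767). Differences below are log2 values with their SE, and positive values are higher in the group named first. Where a group's mean lies at or under the array medians (5.92 to 6.11), signal there is close to background, which can compress a difference from it. Such a difference still carries its sampling error and is not a lower bound. The same holds for falls from a level near the highest value of the table, where a probe set can saturate.

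The study's first question was how the airway epithelium of asthmatics differs from that of healthy people. Asthmatic brushings carried more transcripts of the type 2 list, genes induced by interleukin-13 (fry adjusted p = 2.51e-06), and of the mast cell list (2.54e-06), and fewer of the club cell list (2.11e-05). CLCA1, a secreted product of goblet cells, was higher in asthma by 2.63 ± 0.45 (n = 42 and 28, adjusted p = 0.000189). POSTN, which encodes the matrix protein periostin, was 4.38-fold higher (2.13 ± 0.33), and CST1, a cysteine protease inhibitor, was higher by 2.04 ± 0.36. The healthy means of CLCA1 (4.73) and CST1 (4.54) lay under every array median, so background may compress their differences. CPA3, a protease of mast cell granules, was 3.38-fold higher (1.76 ± 0.29, adjusted p = 9.41e-05). SCGB3A1, a secretoglobin of secretory cells, was lower by 1.08 on the log2 scale (SE 0.21, adjusted p = 0.00134), and 1 of 42 asthmatics lay above the healthy median. Its healthy mean was 13.60, where saturation may compress the fall.

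These rises were uneven between people. CLCA1 had a mean log2 level of 7.35 ± 2.56 (SD, n = 42) in asthma and 4.73 ± 0.26 (SD, n = 28) in health, and 25 of 42 asthmatics exceeded the highest healthy person. The same was so for CST1 in 23 of 42, for CPA3 in 18, for CEACAM5 in 16, for TPSAB1 in 15 and for POSTN in 11. TPSAB1, a mast cell tryptase, lay above the healthy median in 42 of 42 asthmatics.

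**Figure D1:**
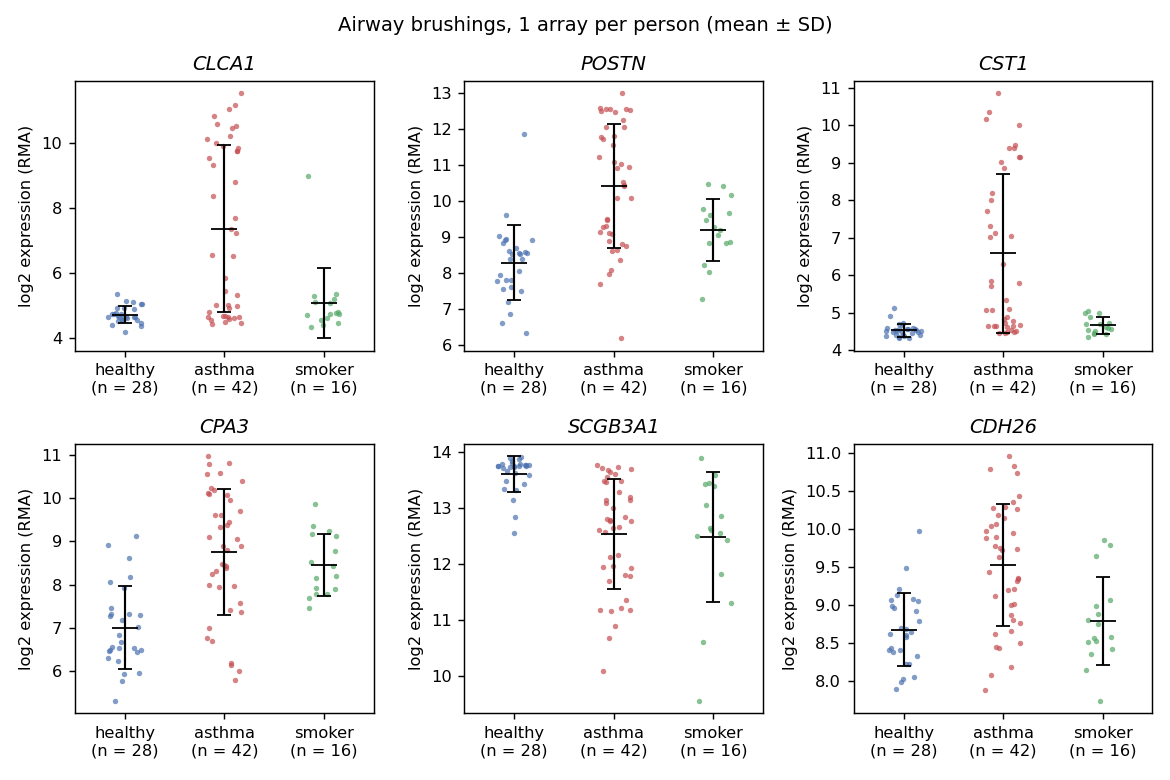
Log2 expression (RMA) of 6 genes in brushings of healthy people, asthmatics and smokers, where each point is a person and bars give the mean ± SD. CLCA1 and CST1 sit near 4.73 and 4.54 in the healthy group and spread upward among asthmatics, and SCGB3A1 spreads downward from a healthy mean of 13.60.

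The type 2 list rose on balance (mean difference 0.60 ± 0.096, fry adjusted p = 2.51e-06, and adjusted p = 0.00568 with an estimated correlation). With sub-study as a block the difference was 0.35 and not called (fry adjusted p = 0.341), nor was it within the mixed sub-study (0.35, 0.251). Both differences rest on the same 7 asthmatics and 11 healthy people, the only sub-study with both groups. The other 14 alternatives called it (2.85e-07 to 0.341 over all 16), but none of those 14 holds sub-study fixed. Of its 23 measured members, 10 rose, 0 fell and 13 did not pass, and 14 rose when adjusted over the list alone. Besides CLCA1, POSTN and CST1, the risers included ITLN1, a lectin of mucus cells (1.27 ± 0.27), CST4 (1.48 ± 0.25), NOS2, the inducible nitric oxide synthase (0.29 ± 0.060), and CCL26, an eosinophil attractant (0.57 ± 0.15, adjusted p = 0.0442). ALOX15, a lipoxygenase, did not pass (0.46 ± 0.14, adjusted p = 0.0733). This list holds POSTN and CLCA1, which were reported from these samples, so its count is not independent evidence.

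Mast cell genes rose together (0.50 ± 0.081, fry adjusted p = 2.54e-06, and adjusted p = 0.00568 with an estimated correlation), and these too were reported from these samples. Of 13 members 7 rose, 10 when adjusted over the list alone, with TPSB2 at 1.13 ± 0.18, TPSAB1 at 0.90 ± 0.14 and SLC18A2, a vesicular monoamine transporter, at 0.80 ± 0.15 (1 of its 2 probe sets had that direction). The eosinophil list rose by 0.10 ± 0.028 (fry adjusted p = 0.00301), with CLC, the Charcot-Leyden crystal protein, as its 1 member to pass (0.55 ± 0.14). The dendritic and Langerhans cell list rose by 0.11 ± 0.026 (fry adjusted p = 0.000653) with CCL22, a chemokine, at 0.19 ± 0.048. With an estimated correlation the eosinophil list had an adjusted p = 0.187 and the dendritic list an adjusted p = 0.116. When adjusted over the list alone, 3 of 10 eosinophil and 5 of 11 dendritic members rose.

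In the epithelium, the club cell list fell by 0.40 on the log2 scale (SE 0.076, fry adjusted p = 2.11e-05, and adjusted p = 0.00213 with an estimated correlation). Of 10 members 3 fell and 0 rose, 6 falling when adjusted over the list alone. They were SCGB3A1, CYP2F1 (-0.46 ± 0.12) and CYP2B6 (-0.38 ± 0.083), the last 2 being cytochromes that oxidise foreign compounds. SCGB1A1, the main club cell secretoglobin, had a difference of -0.36 ± 0.098 (adjusted p = 0.0505). The goblet cell list rose by 0.23 ± 0.065 (fry adjusted p = 0.00394, but adjusted p = 0.187 with an estimated correlation), and 1 of its 15 members passed, the adhesion protein CEACAM5 (1.25 ± 0.25), against 2 when adjusted over the list alone. The mucins MUC5AC (0.19 ± 0.10, adjusted p = 0.315), MUC5B (0.11 ± 0.046, adjusted p = 0.199) and MUC2 (0.11 ± 0.049, adjusted p = 0.252) did not pass, and the 2 probe sets of MUC5B pointed in opposite directions. With their mean, MUC5B was called lower (-0.39, adjusted p = 0.00068; 0.00068 to 0.662 over its alternatives), so its direction is not settled. Squamous genes rose by 0.10 ± 0.042 on balance (fry adjusted p = 0.0102, adjusted p = 0.237 with an estimated correlation), with CNFN, a cornified envelope protein, as the 1 of 15 members to pass (0.41 ± 0.094; 3 of 15 when adjusted over the list alone).

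Among the largest falls were APELA, a peptide ligand of the apelin receptor (-1.11 ± 0.24), SHISA2 (-1.04 ± 0.21), TMEM45A (-0.98 ± 0.15) and C3, the central complement protein (-0.95 ± 0.20). SCNN1G, a subunit of the epithelial sodium channel (-0.93 ± 0.15), LTF, the iron-binding protein lactoferrin (-0.82 ± 0.21), STEAP4, a metalloreductase (-0.75 ± 0.13), the formin FHOD3 (-0.74 ± 0.15) and the cadherin CDH2 (-0.75 ± 0.20, 1 of 2 probe sets) also fell. The remaining large rises were P2RY14, a receptor for UDP-sugars (1.35 ± 0.25), and the non-coding PCAT19 (1.17 ± 0.21). PRB1, a salivary proline-rich protein, rose by 0.38 ± 0.097. Smaller falls included the insulin signalling adaptor IRS2 (-0.43 ± 0.078) and the mitotic protein CENPF (-0.29 ± 0.075). The ciliated, basal, ionocyte, gland, stroma, red blood cell, neutrophil, T and NK, B and plasma, macrophage, AHR, NRF2, glucocorticoid, NF-kB, interferon, cell cycle, unfolded protein and immediate early lists were not called (mean differences from -0.13 to 0.11, fry adjusted p from 0.0643 to 0.97). Of these the stroma list was called higher under 3 of 16 alternatives (0.0257 to 0.776) and the glucocorticoid list lower under 1 (0.0352 to 0.765). FOXJ1, the regulator of ciliated cells (-0.04 ± 0.081), and KRT5, the basal keratin (0.22 ± 0.17), were among the preset genes that did not pass.

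In all, limma called 198 of 19739 genes, 135 higher and 63 lower, of which 10 and 3 changed over 2-fold, and 3420 genes had an unadjusted p under 0.05. After quantile normalization 117 genes were higher and 102 lower. Within the mixed sub-study (7 asthmatics, 11 healthy people), and with sub-study as a block, limma called 0 genes, with 1329 and 1248 at an unadjusted p under 0.05. The 198 genes had the same direction there, at a median of 0.946 times the size, which is partly built in because these arrays took part in the call (CLCA1 2.27, CPA3 1.57, POSTN 1.24, SCGB3A1 -1.42, but CCL26 0.01). Of the 7 called lists, the club cell list was called within that sub-study (-0.39, fry adjusted p = 0.0037), while the mast cell list (0.50) was called with sub-study as a block alone (fry adjusted p = 0.037). The type 2 (0.353), eosinophil (0.057), dendritic (0.123), goblet (0.134) and squamous (0.0107) lists were called in neither, with the same differences in both. All of these but the dendritic difference were smaller than in the main fit, most of all the squamous one. The eosinophil list was also not called without the dimmest 40% of genes (difference 0.067, fry adjusted p = 0.194), nor the goblet list with only the 10 unpaired asthmatics (0.187, 0.312). Their adjusted p over the alternatives ran from 0.000525 to 0.341 and from 0.000151 to 0.745. Leaving out 1 person moved the count between 115 and 441. The counts beyond 1.5 times the full one were 319, 299, 346, 441, 382 and 115 without asthma replicates 9, 29, 33, 35, 38 and 42, and 128, 331, 128 and 401 without healthy replicates 5, 7, 8 and 21.

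For the second question, smokers against healthy people, the data show a large rise of the NRF2 and AHR target lists (fry adjusted p = 6.96e-23 and 3.17e-16) and a fall of the club cell list (3.96e-05, but adjusted p = 0.0883 with an estimated correlation). AKR1B10, an aldo-keto reductase, was higher in smokers by 3.60 ± 0.18 (n = 16 and 28, adjusted p = 1.02e-30), and 15 of 16 smokers exceeded the highest healthy person. CYP1B1, a cytochrome induced by smoke hydrocarbons, was higher by 2.77 ± 0.24 (12 of 16), and GPX2, a glutathione peroxidase, was 5.17-fold higher (2.37 ± 0.18, 14 of 16). Background may compress the differences of AKR1B10 and CYP1B1. LTF fell by 2.27 on the log2 scale (SE 0.27, adjusted p = 8.95e-10) and lay below the lowest healthy person in 15 of 16 smokers. SLIT2, a secreted guidance ligand, fell by 2.23 (SE 0.24, 12 of 16).

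The NRF2 list, genes of the oxidant response, rose by 1.03 ± 0.072 (fry adjusted p = 6.96e-23, and adjusted p = 2.9e-07 with an estimated correlation). Of its 27 members 23 rose and 0 fell, also when adjusted over the list alone, among them the cystine transporter SLC7A11 (2.04 ± 0.16), the alcohol dehydrogenase ADH7 (1.79 ± 0.19) and the quinone reductase NQO1 (1.43 ± 0.14). The AHR list, targets of the aryl hydrocarbon receptor, rose by 0.70 ± 0.056 (fry adjusted p = 3.17e-16, and adjusted p = 6.66e-05 with an estimated correlation). Of 12 members 6 rose and 0 fell (7 when adjusted over the list alone), including ALDH3A1, an aldehyde dehydrogenase (2.25 ± 0.25), CYP1A1 (0.71 ± 0.16) and AHRR, the receptor's repressor (0.30 ± 0.049). NQO1 belongs to both lists. Other large rises were CEACAM5 (2.32 ± 0.33, 5.00-fold), CABYR (1.99 ± 0.15), the small mucin-like MUCL1 (1.86 ± 0.22) and SPP1, which encodes osteopontin (1.63 ± 0.20).

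**Figure D2:**
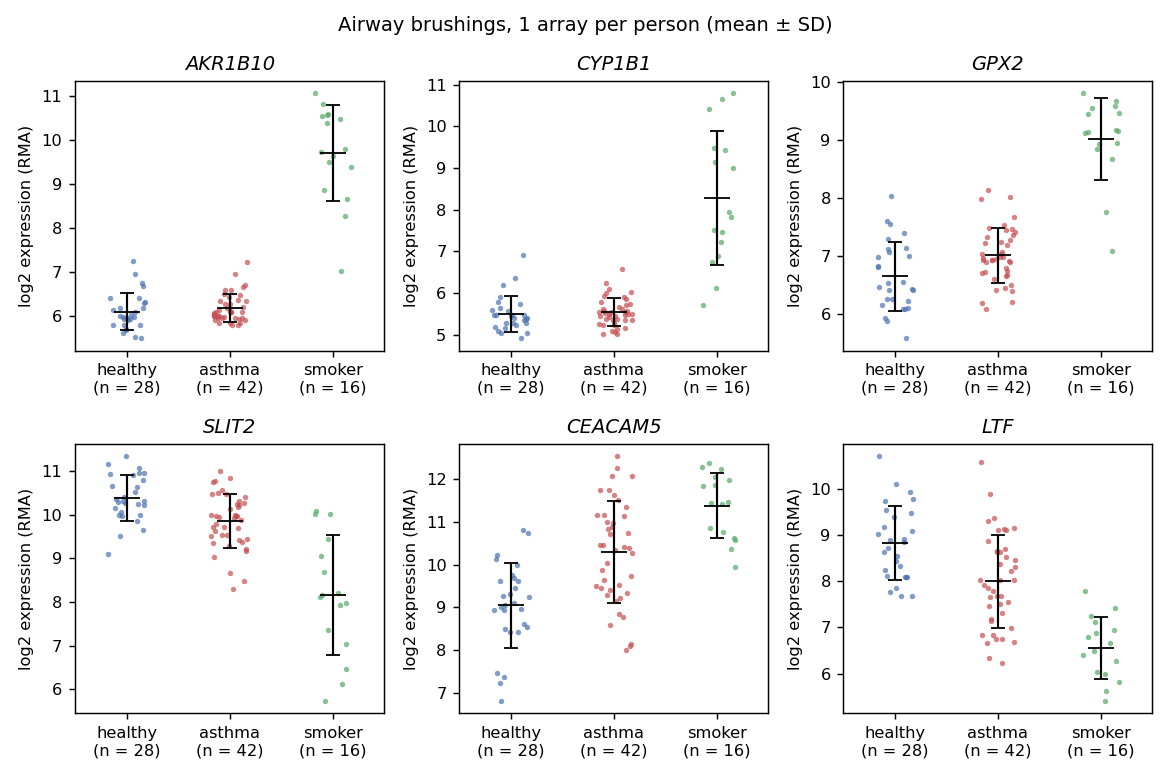
Log2 expression (RMA) of 6 genes in brushings of healthy people, asthmatics and smokers, where each point is a person and bars give the mean ± SD. AKR1B10 averages 9.70 in smokers against 6.18 in asthmatics, while LTF averages 6.55 in smokers against 8.82 in healthy people.

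The goblet cell list rose by 0.36 ± 0.083 (fry adjusted p = 9.11e-05, but adjusted p = 0.104 with an estimated correlation): 5 of 15 members rose and 1 fell (8 and 1 when adjusted over the list alone). MUC5AC, the main mucin of goblet cells, rose by 0.75 ± 0.13 (adjusted p = 9.91e-06), as did the goblet cell regulator SPDEF (0.44 ± 0.14) and CEACAM6 (0.58 ± 0.13), while FCGBP, a mucus protein that binds IgG, fell (-1.18 ± 0.24). The squamous list rose by 0.20 ± 0.054 (fry adjusted p = 3.96e-05, adjusted p = 0.0883 with an estimated correlation), with 9 of 15 members up over all genes and over the list alone, such as SPRR3 (0.65 ± 0.22), SPRR1B (0.58 ± 0.17) and MAL (0.38 ± 0.11). The ionocyte and neuroendocrine list rose by 0.13 ± 0.037 (fry adjusted p = 0.000263, adjusted p = 0.123 with an estimated correlation), through the ionocyte genes ATP6V0D2, a proton pump subunit (1.00 ± 0.18), and ASCL3 (0.44 ± 0.083), 2 of 11 members, or 3 when adjusted over the list alone.

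The club cell list fell by 0.32 on the log2 scale (SE 0.097, fry adjusted p = 3.96e-05, adjusted p = 0.0883 with an estimated correlation), with 5 of 10 members down by either adjustment. SCGB1A1 fell by 0.81 (SE 0.13, adjusted p = 1.4e-06), a fall that saturation may compress, and lay below the lowest healthy person in 13 of 16 smokers. SCGB3A1 (-1.13 ± 0.27), CYP2F1 (-0.66 ± 0.15) and the protease inhibitor SLPI (-0.46 ± 0.096) fell too. The ciliated list fell by 0.25 on the log2 scale (SE 0.076, fry adjusted p = 0.00385, adjusted p = 0.195 with an estimated correlation), with 7 of 23 members down, or 9 when adjusted over the list alone. Its fallers included the axonemal dynein DNAH5 (-0.69 ± 0.10), SPAG6 (-0.60 ± 0.12), ODAD2 (-0.73 ± 0.15, 1 of 2 probe sets) and DNAAF11 (-0.42 ± 0.099), while FOXJ1 did not pass (-0.21 ± 0.10, adjusted p = 0.161). Without the 4 arrays of low agreement, 3 of them from smokers, the ciliated list difference was -0.09 and no longer called (fry adjusted p = 0.281).

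The glucocorticoid list fell by 0.21 on the log2 scale (SE 0.047, fry adjusted p = 5.73e-05, adjusted p = 0.0883 with an estimated correlation). Of 23 members 8 fell and 1 rose (9 and 2 when adjusted over the list alone). The metal-binding metallothioneins MT1X (-0.70 ± 0.19) and MT2A (-0.67 ± 0.20) fell, with PDK4, a kinase of glucose oxidation (-0.58 ± 0.15), and IRS2 (-0.53 ± 0.10), while FKBP5 did not pass (-0.27 ± 0.23).

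Mast cell genes rose in smokers too (0.44 ± 0.105, fry adjusted p = 0.000126, adjusted p = 0.104 with an estimated correlation), in 7 of 13 members (9 when adjusted over the list alone), such as CPA3 (1.46 ± 0.37), TPSB2 (1.01 ± 0.24), TPSAB1 (0.74 ± 0.18) and the stem cell factor receptor KIT (0.69 ± 0.17). Rises were also called for the dendritic list (0.12 ± 0.033, fry adjusted p = 0.000262, adjusted p = 0.119 with an estimated correlation, 3 of 11 members, 5 over the list alone), with the Langerhans marker CD1A at 0.30 ± 0.072. The dendritic list was not called without the dimmest 40% of genes (0.142, fry adjusted p = 0.134), though that difference was no smaller than in the main fit. Its adjusted p ran from 7.61e-05 to 0.134 over the alternatives. The stroma list rose by 0.09 ± 0.034 (fry adjusted p = 0.000218, adjusted p = 0.119 with an estimated correlation, 3 of 12 members, 5 over the list alone), with the smooth muscle protein TAGLN at 0.19 ± 0.061. The red blood cell list rose by 0.13 ± 0.071 (fry adjusted p = 0.0226, adjusted p = 0.389 with an estimated correlation, 0 of 7 members by either adjustment). It lost its call under 5 of 14 alternatives, among them quantile normalization (0.172), centring (0.178) and sub-study as a block (0.121), with adjusted p from 0.000167 to 0.486 over all of them.

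The type 2 list was not called in smokers (0.08 ± 0.124, fry adjusted p = 0.277), except when only the 2 groups were fitted (0.0495; 0.0495 to 0.595 over its alternatives). POSTN (0.91 ± 0.43, adjusted p = 0.139), CLCA1 (0.35 ± 0.57) and CST1 (0.12 ± 0.46) did not pass, and ALOX15 fell (-0.49 ± 0.18, adjusted p = 0.0488). The NF-kB list was not called (fry adjusted p = 0.218) except as lower with the ciliated list mean as a covariate (0.022; 0.022 to 0.585 over its alternatives). Its members moved both ways, with the neutrophil attractants CXCL6 (-0.90 ± 0.19), CXCL2 (-0.73 ± 0.20) and CXCL1 (-0.53 ± 0.11) lower and the calcium-binding S100A9 higher (0.51 ± 0.15). The gland list was not called (-0.22 ± 0.049, fry adjusted p = 0.464), but it was called lower within the smoking sub-study (-0.245, 0.0302) and without the dimmest 40% of genes (-0.354, 0.0102), with adjusted p from 0.0102 to 0.643 over its alternatives. Its members moved in both directions, with LTF and PIP (-1.13 ± 0.25) lower and AZGP1 higher (0.80 ± 0.16). The neutrophil, eosinophil, T and NK, B and plasma, macrophage, basal, interferon, cell cycle, unfolded protein and immediate early lists were not called either (mean differences from -0.08 to 0.22, fry adjusted p from 0.1 to 0.996), and the alarmin IL33 fell (-0.50 ± 0.15). Further large falls were the transcription cofactor VGLL3 (-2.20 ± 0.30), C3 (-1.85 ± 0.26), APELA (-1.78 ± 0.31), the transcription factors NPAS3 (-1.66 ± 0.21, 7 of 9 probe sets) and PLAG1 (-1.52 ± 0.15), the vitamin C transporter SLC23A1 (-1.64 ± 0.18), SEC14L3 (-1.57 ± 0.24) and CNTD1 (-1.53 ± 0.21). The chemokine CX3CL1 fell as well (-0.72 ± 0.12).

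limma called 2670 genes between smokers and healthy people, 1094 higher and 1576 lower, 35 and 50 of them over 2-fold, and after centring of each array 658 were higher and 1964 lower. Within the smoking sub-study (16 smokers, 15 healthy people) it called 1087, with AKR1B10 at 3.53, CYP1B1 at 2.75 and LTF at -2.19, and with sub-study as a block 1496. The 2670 genes had the same direction within that sub-study, which is largely built in because it holds all 16 smokers and 15 of the 28 healthy people of that call. There the ciliated (-0.270, fry adjusted p = 0.0694) and ionocyte (0.103, 0.0594) lists were no longer called, though the ciliated difference was no smaller in size than in the main fit. Without the 4 arrays of low agreement, 1707 genes were called.

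Asthmatics and smokers were also compared with each other. Named genes differed in both directions: CLCA1 by 2.27 ± 0.54, CST1 by 1.92 ± 0.43, ITLN1 by 1.49 ± 0.32, POSTN by 1.22 ± 0.40 (adjusted p = 0.0304) and ALOX15 by 0.95 ± 0.17 in asthma, against AKR1B10 at -3.52 ± 0.16, ALDH3A1 at -2.87 ± 0.23 and CYP1B1 at -2.74 ± 0.22. The type 2 list was higher in asthma by 0.52 ± 0.116, with 10 of 23 members higher and 1 lower, 11 and 1 when adjusted over the list alone (fry adjusted p = 0.00754, but adjusted p = 0.537 with an estimated correlation). Lower in asthma were the NRF2 list (-0.99 ± 0.068, 24 of 27 members, 25 over the list alone, fry adjusted p = 1.33e-23) and the AHR list (-0.71 ± 0.052, 6 of 12 members lower, and 7 lower and 1 higher over the list alone, fry adjusted p = 1.94e-17), and both calls held with an estimated correlation. So did the lower ionocyte and neuroendocrine list (-0.20 ± 0.035, 3 of 11 members, 4 over the list alone, adjusted p = 0.0337 with an estimated correlation).

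SLIT2 (1.70 ± 0.23), VGLL3 (1.52 ± 0.28), LTF (1.44 ± 0.26), FCGBP (1.35 ± 0.22) and IL33 (0.75 ± 0.14) were higher in asthmatics than in smokers. MUC5AC (-0.56 ± 0.12), CEACAM5 (-1.08 ± 0.31), the secreted protein MSMB (-0.97 ± 0.22) and the macrophage mannose receptor MRC1 (-0.94 ± 0.30) were lower. The glucocorticoid list was higher (0.15 ± 0.044, fry adjusted p = 0.00614) and the squamous list lower (-0.10 ± 0.051, fry adjusted p = 0.045), each with an adjusted p = 0.537 with an estimated correlation. After quantile normalization neither the glucocorticoid list (0.096, fry adjusted p = 0.0872) nor the squamous list (-0.098, 0.108) was called. Of their members, 6 of 23 were higher and 0 lower (7 and 0 over the list alone), and 1 of 15 was higher and 3 lower by either adjustment. The squamous list lost its call under 6 of 10 alternatives (0.00961 to 0.79) and the glucocorticoid list under 1 (0.00035 to 0.0872). Some lists gained a call: stroma, lower, under 5 alternatives, and eosinophil and ciliated, higher, under 3 each. Goblet, lower, and gland, higher, were called under 1 each. The mast cell genes did not differ by the test (0.06 ± 0.098, fry adjusted p = 0.964; TPSAB1 0.16 ± 0.17, CPA3 0.29 ± 0.35). limma called 2888 genes, 1959 higher and 929 lower in asthma (1396 and 1204 after quantile normalization), and 1365 without the 4 arrays of low agreement or 1751 without smoker replicate 1. No sub-study held both groups, so sub-study and group cannot be told apart in this comparison.

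Changes shared by asthma and smoking were counted against the same healthy people. Of the genes called in both, 42 were higher in both (7.48 expected from independent lists), among them CEACAM5, CPA3, TPSAB1, TPSB2 and KIT, and 33 were lower in both (5.03 expected), among them SCGB3A1, LTF, C3, TMEM45A, SCNN1G and IRS2. None was higher in asthma and lower in smokers (10.8 expected), and 2 were lower in asthma and higher in smokers (3.49 expected, two-sided Fisher's exact p = 0.584). Shared healthy people alone can make such effects correlate. Across genes, which are not independent replicates, the effects correlated with r = 0.355, while simulated data without any effect gave a median of 0.477 (0.0149 to 0.855). The covariance was 0.00883, against a simulated median of 0.00318 (0.000114 to 0.0175). For the overlap of calls, simulated data without any effect gave a median of 0 and a highest count of 0. Few genes pass the threshold without an effect, so this cannot show how far shared healthy people raise the overlap. With the healthy people split at random into separate groups, 1 for each comparison (100 splits), the correlation had a median of 0.197 (-0.217 to 0.489). In those splits a median of 4 genes was higher in both (0 to 14, 0.511 expected) and 6.5 lower in both (0 to 23, 0.436 expected). Fewer controls also meant fewer calls there, with a median of 30.5 genes for asthma and 1342.5 for smokers.

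The treatment question was whether fluticasone changed expression more than placebo did. Fluticasone raised several known targets of glucocorticoids. FKBP5, a partner of the glucocorticoid receptor, rose 4.55-fold relative to placebo (2.18 ± 0.20, n = 19 and 13, adjusted p = 2.57e-08), and it rose in 19 of 19 people on fluticasone and 4 of 13 on placebo. FAM107A (1.49 ± 0.14), TSC22D3, the glucocorticoid-induced leucine zipper (1.34 ± 0.14, 2 of 3 probe sets), and the transcription factor TFCP2L1 (1.62 ± 0.22, 2 of 3 probe sets) rose too. MUC13, a membrane mucin, fell by 1.01 on the log2 scale (SE 0.18, adjusted p = 0.004), and was lower after treatment in 18 of 19 people on fluticasone.

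The glucocorticoid list rose by 0.44 ± 0.063 relative to placebo (fry adjusted p = 6.03e-07, and adjusted p = 4.58e-05 with an estimated correlation). Of 23 members 5 rose and 0 fell, and 10 rose when adjusted over the list alone, with PDK4 at 0.93 ± 0.17. FKBP5 was reported from these samples, so the count is not independent evidence. The type 2 list fell by 0.41 on the log2 scale (SE 0.118, fry adjusted p = 0.0232, but adjusted p = 0.063 with an estimated correlation). Of 23 members 1 fell, or 9 when adjusted over the list alone, and CDH26, a cadherin (-0.65 ± 0.14, adjusted p = 0.0235, 2 of 4 probe sets), passed over all genes. The list was not called with an RNA integrity term (-0.357, fry adjusted p = 0.065), with person as a random block (-0.410, 0.0631) or without pairing (-0.410, 0.419). The other 8 of 11 alternatives called it (0.0123 to 0.419 over all). CLCA1 (-1.24 ± 0.48, adjusted p = 0.459), CST1 (-1.07 ± 0.37, adjusted p = 0.347), POSTN (-1.05 ± 0.48, adjusted p = 0.597) and CPA3 (-0.48 ± 0.27, adjusted p = 0.719) did not pass.

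**Figure D3:**
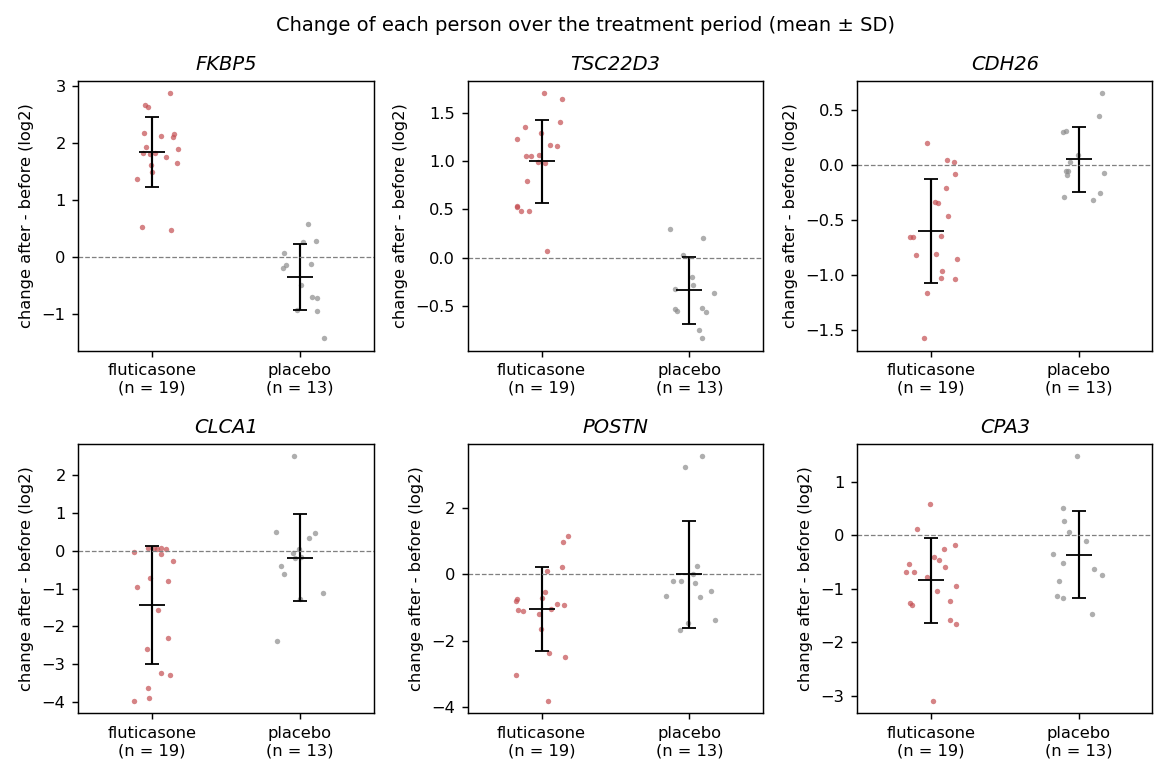
Change in log2 expression after minus before treatment for 6 genes, where each point is a person on fluticasone (n = 19) or placebo (n = 13) and bars give the mean ± SD. FKBP5 rose in 19 of 19 people on fluticasone, by 1.84 on average, against a mean of -0.35 on placebo.

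Other rises relative to placebo were PHACTR3 (1.70 ± 0.24), the growth-arrest protein GAS1 (1.70 ± 0.27, 2 of 3 probe sets), the hydroxycarboxylic acid receptor HCAR3 (1.26 ± 0.22), AHNAK2 (1.05 ± 0.19), the non-coding LINC00964 (1.07 ± 0.19) and LINC01279 (1.02 ± 0.18), and AKR1C1 (0.46 ± 0.11, adjusted p = 0.0402). Falls were CH25H, cholesterol 25-hydroxylase (-0.81 ± 0.15), the interferon-induced IFI27 (-0.67 ± 0.14) and IFI44 (-0.51 ± 0.12), the protease cathepsin C, CTSC (-0.64 ± 0.13), the kinase LYN (-0.51 ± 0.11), the channel subunit KCNE3 (-0.59 ± 0.14), AP2B1 (-0.58 ± 0.12) and FOLH1B (-0.60 ± 0.13). The NRF2 list changed in either direction (fry mixed adjusted p = 0.0022; 1 of 27 members rose, and 2 rose and 4 fell over the list alone) and not on balance (adjusted p = 0.156). The other 22 lists had fry adjusted p from 0.0512 to 0.973. Of these, the dendritic (-0.13, 0.0512), goblet (-0.21, 0.0525) and interferon (-0.26, 0.0664) lists lay near the threshold and were called lower under 6, 4 and 4 of 11 alternatives, with adjusted p from 0.0126 to 0.419 for the first 2 and from 0.021 to 0.419 for the last. The AHR list (-0.08, 0.0664) was called under 1, quantile normalization (0.0494; 0.0494 to 0.587 over its alternatives).

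limma called 76 genes, 63 higher and 13 lower, 11 and 1 over 2-fold, and 1514 genes had an unadjusted p under 0.05. Pairing carried these calls: a fit that ignored it gave 5 genes between the arms, 35 in the fluticasone arm and 0 in the placebo arm. Leaving out placebo replicate 2 gave 47 genes.

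Within the fluticasone arm more genes passed, 198 higher and 149 lower of 347. Beside the rise of FKBP5 (1.84 ± 0.13), TFCP2L1 (1.65 ± 0.14) and the growth factor TGFB2 (0.93 ± 0.10), the asthma-associated genes CLCA1 (-1.42 ± 0.30, lower in 14 of 19 people), CST1 (-1.24 ± 0.24, 16 of 19), P2RY14 (-1.09 ± 0.20) and CPA3 (-0.84 ± 0.17, 17 of 19) fell, while POSTN was lower in 15 of 19 but did not pass (-1.05 ± 0.30, adjusted p = 0.073). The type 2 list fell by 0.38 on the log2 scale (fry adjusted p = 0.00033; 8 of 23 members, 14 over the list alone). The mast cell list fell by 0.24 (fry adjusted p = 0.000253; 3 of 13, 6 over the list alone), the dendritic list by 0.13 (fry adjusted p = 0.00033; 2 of 11, 4 over the list alone) and the goblet list by 0.21 (fry adjusted p = 0.000714; 5 of 15, 9 over the list alone). Between the arms the mast cell list was not called in the main fit or under any of 11 alternatives (fry adjusted p from 0.252 to 0.782 over them). Nor did CLCA1, CST1, POSTN or CPA3 pass between the arms, and each was also lower after treatment in most of the 13 people on placebo. The interferon list fell by 0.30 (fry adjusted p = 0.00033; 7 of 25, 14 over the list alone), and the glucocorticoid list rose by 0.42 ± 0.040 (fry adjusted p = 1.06e-10; 9 of 23, 18 over the list alone). These 6 calls held with an estimated correlation. The call of the type 2 list was lost without pairing (0.0785; 2.78e-05 to 0.0785 over its alternatives).

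Falling members included LAMP3, a marker of mature dendritic cells (-0.44 ± 0.073), the IgE receptor chain FCER1A (-0.32 ± 0.066), SPDEF (-0.28 ± 0.058), the antiviral genes IFIT3 (-0.71 ± 0.19) and OAS2 (-0.47 ± 0.092), and the alarmin IL33 (-0.70 ± 0.13). The T and NK list fell by 0.11 (fry adjusted p = 0.0115, adjusted p = 0.0659 with an estimated correlation) through CD8A (-0.61 ± 0.13) and CD3D (-0.37 ± 0.063), 2 of 13 members by either adjustment. It was not called without the dimmest 40% of genes (-0.08, 0.138) or without pairing (0.185; 0.00172 to 0.185 over its alternatives). The B and plasma list fell by 0.11 (fry adjusted p = 0.0218, adjusted p = 0.0875 with an estimated correlation; 0 of 10 members, 2 over the list alone), and its difference was 0.0153 and not called (adjusted p = 0.471) without the dimmest 40% of genes. That call was lost under 4 of 11 alternatives (0.00661 to 0.471). The basal list changed in either direction (fry mixed adjusted p = 0.00486), with the keratins KRT5 (0.49 ± 0.12) and KRT15 (0.45 ± 0.11) up and IL33 down, 2 and 1 of 13 members, or 6 and 1 over the list alone. NRF2 genes did so too (fry mixed adjusted p = 2.59e-05), with AKR1C2 (0.36 ± 0.085) up and GPX2 (-0.45 ± 0.11) and ADH7 (-0.48 ± 0.13) down, 2 and 4 of 27 members, or 2 and 8 over the list alone. Some lists gained a call on balance: cell cycle, higher, under 3 of 11 alternatives, and basal, higher, and AHR, lower, under 2 each. Red blood cell, higher, and unfolded protein, lower, were called under 1 each.

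In the placebo arm limma called 0 genes, with 1237 at an unadjusted p under 0.05, and eBayes with trend and robust settings also gave 0. No list was called (lowest fry adjusted p 0.0845, for the cell cycle list). The cell cycle list was called higher under 3 of 11 alternatives: without the dimmest 40% of genes (0.0192), with person as a random block (0.0284) and without the 4 arrays of low agreement (0.0317), with 0.0192 to 0.276 over all. The squamous list was called higher under the last of these (0.0317; 0.0317 to 0.841 over its alternatives). Means were -0.18 ± 0.37 for CLCA1 and -0.35 ± 0.16 for FKBP5. These within-arm results were not set against each other except by the test of the arms' difference above.

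**Figure D4:**
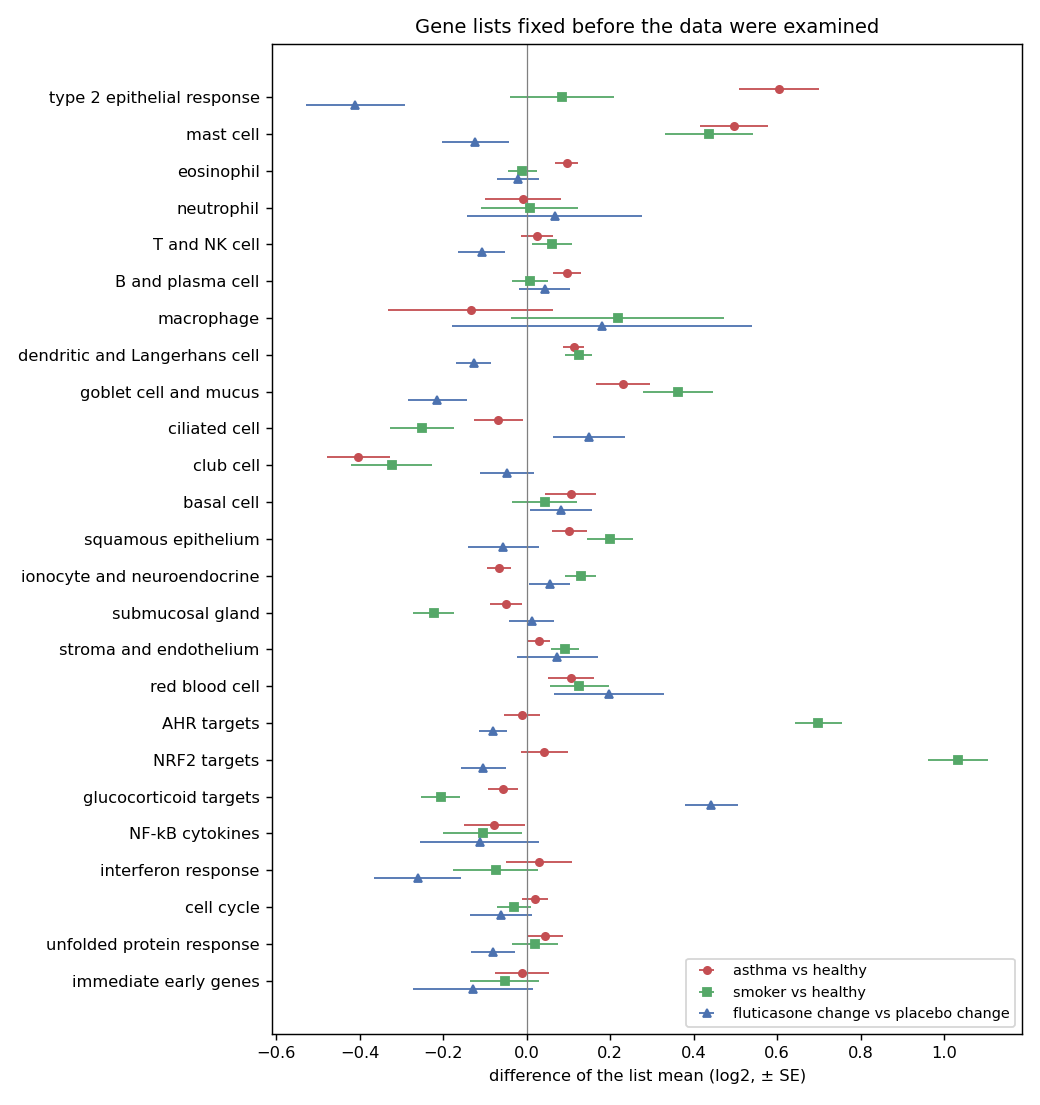
Difference of the mean log2 level of each of 25 gene lists (± SE) in asthma against healthy, smokers against healthy, and the fluticasone change against the placebo change. The NRF2 list reaches 1.03 in smokers, the type 2 list is at 0.60 in asthma and -0.41 in the treatment comparison, and the glucocorticoid list is at 0.44 in the treatment comparison.

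The genes called in asthma were then followed as a set through treatment. Signed by their direction in asthma, so that negative values point towards the healthy level, the 198 genes changed by a mean of -0.15 ± 0.12 (SD, n = 19) on fluticasone, against 0.01 ± 0.10 (SD, n = 13) on placebo. The difference was -0.16 (SE 0.039, permutation p = 0.00021), and 17 of 19 people on fluticasone and 6 of 13 on placebo moved towards healthy. Among single genes, 21 that were higher in asthma fell after fluticasone, such as CDH26, CEACAM5, CLCA1, CPA3, CST1, ITLN1 and P2RY14. Another 9 that were lower in asthma rose, such as SCNN1G, SHISA2 and AKR1C1, and 0 changed in the asthmatic direction. The baseline arrays of the treated people enter both comparisons, so regression to the mean alone brings such overlaps, and no expected count is given for them. With 45 genes called from the 10 asthmatics who were not in the treatment pairs, the difference was -0.29 (permutation p = 0.00068).

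The type 2 list mean also spread more widely among asthmatics (SD 0.546, n = 42) than among healthy people (SD 0.121, n = 28; permutation p = 1e-05, the smallest the draws can give). Of the 28 preset genes tested the same way, 8 had an adjusted p under 0.05: CLCA1 (SD 2.56 against 0.259, adjusted p = 0.00014), CST1 (2.12 against 0.173, 0.00014), SCGB1A1 (0.397 against 0.105, 0.00112), POSTN, TPSAB1, CCL26, NOS2 and TPSB2. Healthy levels of CLCA1, CST1, CCL26 and NOS2 lay under the array medians, where background compresses the SD, and SCGB1A1 lay near the top of the scale. The wider spread of these genes, and of the type 2 list, therefore does not measure heterogeneity apart from their level. The list mean fell in 18 of 19 people on fluticasone (-0.38 ± 0.33, SD) and in 8 of 13 on placebo (0.03 ± 0.31, SD). The change declined with the level before treatment by a slope of -0.691 on fluticasone and -0.051 on placebo, and the difference in slope of -0.640 did not pass (permutation p = 0.0549).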

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

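Among the tests below, those of sub-studies, of club cells and of immune cell lists were chosen only after the result was seen. The tests of shared healthy people and of random splits were chosen before.

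AKR1C1, an aldo-keto reductase that acts on steroids and reactive carbonyls, differed in direction between the disease and the exposure. It was lower in asthmatics than in healthy people (-0.36 ± 0.096, adjusted p = 0.0403) and higher in smokers (1.05 ± 0.12), and the test of the difference gave -1.42 (adjusted p = 3.73e-17). It rose on fluticasone relative to placebo (0.46 ± 0.11, adjusted p = 0.0402). Of its 5 probe sets 4 were lower in asthma, and they share sequence with AKR1C2. NOVA1, an RNA-binding splicing regulator, was also lower in asthma (-0.26 ± 0.060) and higher in smokers (0.31 ± 0.077), with a difference of -0.57 (adjusted p = 5.59e-09). These 2 genes were picked because their effects had opposite directions, so the test of the difference largely restates that choice. Independent lists would bring 3.49 such genes (two-sided Fisher's exact p = 0.584), so 2 is not more than such lists would bring. Both comparisons share their healthy people, though, so their lists are not independent and this count cannot decide.

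Probe sets without a gene name took no part in the gene tests, but some passed the threshold when probe sets were tested one by one. Of 11718 such probe sets, 84 differed between asthma and health, 728 between smokers and health and 1315 between asthma and smokers. In treatment, 16 differed between the arms and 78 changed in the fluticasone arm. Among all 54514 probe sets kept, the counts in the same order were 462, 4999, 6332, 105 and 530. Unnamed probe sets were thus called no more often than probe sets at large.

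Genes called in asthma were drawn mainly from groups of different sub-studies, so a difference between sub-studies was set against a difference of the disease. When asthmatics and healthy people of separate sub-studies alone were compared, 14 genes were called (10 higher, 4 lower), by 1.21 on average. In the mixed sub-study, which took no part in that call, they differed in the same direction by 0.891 on average (7 against 11 people, exact permutation p = 0.00902), 14 of 14 in the called direction. This argues against sub-study as the whole source of those 14 genes. It leaves open the remaining called genes, and a disease effect may account for the 14.

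Genes lower in both asthmatics and smokers, such as SCGB3A1, LTF and C3, could reflect the healthy people that both comparisons share. Of 39 genes called lower in asthma against healthy people outside the smoking sub-study, the mean in smokers against the separate healthy people inside it was -0.233 (permutation p = 0.00278), and 25 of 39 were lower. That argues against shared healthy people as the whole source for these 39 genes as a set. The 39 were not matched to the genes called lower in both groups, and their mean was not set against that of other genes. Fewer club cells in the brushings stay open. The club list median was -0.37 in asthma and -0.27 in smokers, the other genes of the pattern had medians of -0.41 and -0.59, and the wider gap was 0.689 SD of the club members, which does not separate them.

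The mast cell list was called higher in asthmatics and in smokers (in smokers not with an estimated correlation, adjusted p = 0.104), which more immune cells of every type, or sub-studies, could bring about. The mast cell list rose above the mean of the 6 other immune cell lists by 0.466 in asthmatics (permutation p = 1e-05, the smallest the draws can give; the others differed by 0.03) and by 0.369 in smokers (permutation p = 3e-05; the others 0.07). Within sub-studies it was higher by 0.501 in asthmatics (7 against 11 people, exact permutation p = 0.0173) and by 0.5 in smokers (16 against 15 people, permutation p = 1e-05). In the asthmatics that p is for this list alone. After adjustment over the 25 lists fry did not call it within the sub-study (adjusted p = 0.183), and called it with sub-study as a block (0.0374; 6.39e-07 to 0.183 over its alternatives). The mast cell list was picked because it rose, and whether the other lists lie close to background, where rises are compressed, was not tested. Its rise above them therefore cannot decide on more immune cells of every type. Sub-studies are argued against as the whole source in smokers and, with less support, in asthmatics. A rise in mast cells, or in their transcripts per cell, is a candidate explanation that these arrays cannot resolve.

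Random splits of the same arrays into groups of the same sizes asked whether chance gives as many genes, with 100 splits per comparison, the real one included. For asthma against health 2 of 100 splits gave at least the real 198, and the highest other gave 1461. For smokers against health 1 of 100 reached 2670 (highest other 917), and for asthma against smokers 2 of 100 reached 2888 (highest other 3609). Those shares make chance unlikely for these 3 as a grouping of single arrays, but 100 splits cannot exclude it. The splits ignore sub-study, though, so a difference between sub-studies is not excluded by them: with sub-study as a block limma called 0 genes for asthma and 1496 for smokers, and no sub-study held both asthmatics and smokers. The splits with 1461 and 3609 genes lay far above the medians of 0, and what sets them apart was not tested. In the treatment pairs 1 of 100 splits of the arms reached 76 (highest other 2), and 1 of 100 sign changes reached 347 in the fluticasone arm (highest other 3), so chance is unlikely for both. In the placebo arm the real count was 0, which 100 of 100 splits reach by definition (highest other 12), so they decide nothing there.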

How the results depend on the processing

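Alternatives that left out the 4 low-agreement arrays, added the macrophage list mean, or left out each array in turn were chosen only after the result was seen. Most results kept their direction and their side of the threshold: 3945 of 4379 values of named genes and 1728 of 1816 values of lists did so, 398 and 38 fell short of the threshold, and 34 and 49 newly passed it. The asthma count of 198 was the least stable. It became 107 without the dimmest 40% of genes, 346 with the mean of all probe sets of a gene, 336 with all probe sets tested, 1946 with array quality weights, 669 with the ciliated list mean as a covariate, 127 without the sub-study of 2 healthy people, 45 with only the 10 unpaired asthmatics, and 0 with sub-study as a block or within the mixed sub-study (1248 and 1329 genes at an unadjusted p under 0.05). The smoker count of 2670 became 1496 with sub-study as a block, 1087 within the smoking sub-study and 1707 without the 4 low-agreement arrays, and the count between asthma and smokers of 2888 became 1365 without those arrays. Between the arms, 76 became 130 with array quality weights, 5 with no replicate block and 38 with person as a random block. In the fluticasone arm 347 became 734 with weights and 35 with no replicate block, and in the placebo arm 0 became 1 with person as a random block. Subsets of people test fewer samples; otherwise the cause was not tested. Leave-one-out counts ran from 115 to 441 for asthma, from 1751 to 3731 between asthma and smokers, and from 47 to 105 between the arms. Scaling moved the balance of directions: the 135 higher and 63 lower genes in asthma became 117 and 102 after quantile normalization and 86 and 82 after centring, the 1094 and 1576 in smokers became 658 and 1964 after centring, and the 1959 and 929 between asthma and smokers became 1396 and 1204 after quantile normalization and 2297 and 634 after centring. MUC5B reversed with the mean of its probe sets, to -0.39 in asthma (adjusted p = 0.00068) and -0.48 in smokers (adjusted p = 9.39e-05), because its 2 probe sets point in opposite directions. The B and plasma list in the fluticasone arm reversed to 0.0153 (adjusted p = 0.471) without the dimmest genes, which removes members. The eosinophil list in asthma was no longer called without them either (adjusted p = 0.194). The set of asthma genes under treatment, the spread of the type 2 list and the difference in its slope kept their side of the threshold under each alternative run for them, with differences of -0.15 to -0.30 (permutation p from 0.00014 to 0.00068), 0.28 to 0.38 (p = 1e-05, the smallest the draws can give) and -0.61 to -0.77 (p from 0.0514 to 0.0631). The correlation of asthma and smoking effects was 0.355, 0.372 after quantile normalization and 0.197 with separate healthy people. Signal close to background limits small changes of dim genes.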

Other observations

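The genes in these paragraphs, apart from the preset CYP1B1, were picked only after their values were seen, and no test beyond the limma fits and overlap tests was run on them. The comparisons of sub-studies at the end were also chosen only after the result was seen. No list of the functions named here was tested, so each value stands for its gene alone. The cytochromes CYP2A13, CYP2J2 and CYP4X1 were lower in both asthmatics and smokers, unlike CYP1B1, which was higher in smokers (2.77 ± 0.24). CYP2A13 was lower by -0.46 ± 0.11 in asthma (adjusted p = 0.0214) and -0.77 ± 0.14 in smokers, and CYP2J2 by -0.33 ± 0.087 and -0.54 ± 0.11. CYP4X1 was lower by -0.48 ± 0.11 in asthma and -1.33 ± 0.14 in smokers, and it rose on fluticasone relative to placebo (0.94 ± 0.19, adjusted p = 0.0162). FYB2 followed the same course, with -0.41 ± 0.11 in asthma (adjusted p = 0.0495), -0.89 ± 0.14 in smokers and 0.85 ± 0.19 on fluticasone relative to placebo (adjusted p = 0.025). Besides these and AKR1C1, no gene that was lower in asthma rose in the test between the arms, where 0.201 such genes were expected and 3 were found (two-sided Fisher's exact p = 0.00107). Of genes higher in asthma 1 fell between the arms, CDH26, where 0.0889 were expected (two-sided Fisher's exact p = 0.0854). Fisher's test treats genes as independent, which they are not, so these p-values do not measure chance here.

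INSR, the insulin receptor, was lower by -0.19 ± 0.044 in asthma and -0.35 ± 0.057 in smokers, as was its adaptor IRS2. SCNN1G, the sodium channel subunit, was lower by -0.93 ± 0.15 in asthma and -1.21 ± 0.19 in smokers. SCNN1G rose within the fluticasone arm (0.45 ± 0.089, adjusted p = 0.00253) but did not pass between the arms (0.55 ± 0.14, adjusted p = 0.0712). In the other direction, the mitochondrially encoded cytochrome oxidase transcripts COX1 (0.22 ± 0.052 in asthma, 0.34 ± 0.067 in smokers) and COX3 (0.30 ± 0.075 and 0.43 ± 0.096) were higher in both groups, and COX3 did not pass in asthma after quantile normalization (adjusted p = 0.0516). The directions of all genes in these paragraphs were the same after quantile normalization and after centring. Neither setting holds sub-study fixed: with sub-study as a block limma called 0 genes for asthma, so none of these asthma calls held there. Asthmatics and smokers were also set against the same healthy people.

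Healthy people of the smoking sub-study (15) and of the mixed sub-study (11) were compared with each other, as were asthmatics of the treatment sub-study (35) and of the mixed sub-study (7). limma called 0 genes in each, with 1514 and 1234 genes at an unadjusted p under 0.05, and no other tool was run on them. Asthmatics against healthy people within the mixed sub-study likewise gave 0 calls, with 1329 genes at that level. The 0 calls therefore do not show that the sub-studies are alike.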
